A study of Mus musculus with 9 samples.

How the data were processed

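Total RNA from 9 mouse liver samples was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 1 array per sample. Per the labels, 4 samples were livers of monotransgenic mice that carried a Cre-inducible Notch1 intracellular domain (NICD) in the Rosa26 locus without Cre. The other 5 samples were hepatocellular carcinomas (HCC) of bitransgenic mice in which Cre under the alpha-fetoprotein (AFP) promoter switched that NICD on. All mice were 6 to 12 months old and of a hybrid 129 x C57BL/6 background, per the labels. Sex and litter were not given in the sources used here.

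The deposited values are probe set intensities on a linear scale, summarised with RMA per the submitters' processing notes. RMA corrects background, quantile-normalises probes between arrays and summarises each probe set by median polish. GenePattern and R were used for preprocessing and analysis, per the labels of the series. Tool versions and probe set annotation were not given in the sources used here. The linear scale was read from the values themselves, which ran from 3.91 to 21468 with array medians between 91.5 and 101 intensity units. The intensities were therefore transformed to log2 before any test, and no pseudocount or floor was applied. Scanner files were not used here, so the RMA step could not be repeated, and no scan date was examined. Detection calls were not used either, so a low intensity is not a statement that a transcript was absent.

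The value table held 35512 probe sets and no column outside the 9 samples. Probe sets were named through the platform annotation of the array, with symbols checked by Entrez identifier against a RefSeq gene table of the GRCm38.p6 assembly, which was used for names only. In that annotation 21789 probe sets had 1 gene symbol, 1621 had several and 12102 had none, and 21698 of those with 1 symbol matched the gene table. Only probe sets with 1 symbol entered the gene tests. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over all arrays was kept, which left 19938 genes. A probe set reports the transcripts that its probes match, so paralogs such as the Cyp2b, Cyp2c, Cyp4a and Acot genes can share signal and are named as uncertain.

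HCC and control liver were compared with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) on log2 intensity over all 9 arrays with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 19938 genes and an adjusted p threshold of 0.05. A second count required a log2 fold change of at least 1, which is 2-fold. The labels name separate mice per genotype group but do not tie each array to 1 animal, so the p-values measure the spread between these arrays. Gene sets were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over 32 lists as 1 family, together with camera with an estimated correlation, camera on ranks and fry. The list score of an array is the mean, over a list, of each gene's log2 intensity minus its mean in the control livers. List scores and distances of arrays to their group mean were compared by exact permutation over the 126 splits of 9 arrays into groups of 4 and 5, whose smallest two-sided p is 0.00794. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

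The following choices were made before the data were examined: the test, the probe set rule, the 32 lists of 521 members (466 measured on a probe set of 1 gene, 18 of the others only on a probe set of several genes), the named genes and the alternatives. The named genes were Notch1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members per list with the largest change past the threshold, or else the member with the smallest adjusted p. Clone-like symbols were passed over for naming. Other list members are given as examples and were chosen after their values were seen. The alternatives were a filter that kept the genes with a mean above the median, quantile normalisation of the deposited values, subtraction of array medians, eBayes with trend and robust estimation, array weights, the mean of all probe sets of a gene, every probe set on its own, the replicate number as a block, the mean of the Y-linked transcripts as a covariate, and leaving out each array in turn. The Xist level as a covariate was added after seeing the data. The planned Y-linked mean used 3 transcripts, since Ddx3y was not analysed here.

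The fit was tested on simulated data with the real genes' means and each group's own spread, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 among 19938. For the comparison of HCC with control liver it recovered 81% and 94% of them, with median estimates of 1.03 and 1.98. It made 18 false calls beside the 81 and 94 genes recovered, a larger share than the adjusted p threshold allows on average. With the spread of the control livers simulated instead, it made 12 false calls beside 84 and 98 genes recovered. The calls on the real data may therefore hold more false ones than the threshold implies. No array was a copy of another, since in each of the 36 pairs of arrays at most 5.11% of probe sets had equal values. For arrays there is no read depth, and the number of arrays per group limits the precision.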

Results

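Expression was compared between 5 hepatocellular carcinomas (HCC) that arose in mice with AFP-Cre-driven, constitutively active Notch1 (NICD) and 4 livers of monotransgenic control mice. NICD is the part of the Notch1 receptor that moves to the nucleus and switches on target genes. The values are RMA intensities of 19938 genes, given below on the log2 scale as mean ± SD, with n = 4 control arrays and n = 5 HCC arrays. Median intensity lay between 91.5 and 101 linear units on the 9 arrays. The question of the design was how liver tumours with constitutive Notch signalling differ in expression from control liver.

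The largest rises in HCC were of Akr1c18, a steroid-metabolising aldo-keto reductase, which went from 5.25 ± 0.37 to 10.93 ± 1.15 (51.1-fold, SE of the log2 change 0.53, adjusted p = 0.00561), and of Bicc1, an RNA-binding protein of renal and biliary epithelium, which went from 7.03 ± 0.41 to 10.95 ± 0.77 (15.1-fold, adjusted p = 0.00561). Lpl, the lipoprotein lipase, rose 10.7-fold (6.65 ± 0.40 to 10.07 ± 0.73, adjusted p = 0.00748), and Scd2, a stearoyl-CoA desaturase of low expression in adult liver, rose 9.22-fold (6.30 ± 0.13 to 9.51 ± 0.73, adjusted p = 0.00729). The largest fall was of Cyp2b9, a cytochrome P450 with female-biased expression in mouse liver, from 12.27 ± 0.73 to 6.59 ± 2.04 (51.1-fold, log2 change -5.68, SE 0.94, adjusted p = 0.0382). Mfsd2a, a transporter of lysophospholipids, fell 16.6-fold (10.84 ± 0.32 to 6.78 ± 1.39, adjusted p = 0.0344), and Nt5e, the ectonucleotidase CD73, fell 6.23-fold (8.76 ± 0.61 to 6.13 ± 0.46, adjusted p = 0.0155). In limma, 171 genes were higher and 32 lower in HCC, of which 108 and 19 changed at least 2-fold, and none of these 203 genes overlapped between the groups.

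The other large rises were of the tetraspanin Tspan8 (log2 change 3.68), Tmem45a (3.66), Wfdc3 (3.63), D17H6S56E-5 (3.31), the ubiquitin-like modifier Ubd (3.30), Calr4 (3.24), the centromere protein Cenph (3.02) and the surface glycoprotein Cd24a (2.93), with adjusted p between 0.00561 and 0.0497. A second probe set of Wfdc3 gave -0.048 (adjusted p = 0.768), so this rise rests on 1 probe set. The other large falls were of Acot3 (-2.33), Chic1 (-2.28), the phosphatidate phosphatase Lpin1 (-2.28), the cytosolic aspartate aminotransferase Got1 (-2.24), Gramd1c (-2.06), the liver collectin Colec10 (-2.05), Rcan2 (-1.79), Acot4 (-1.71) and Tox (-1.52), with adjusted p between 0.0194 and 0.0497. Acot3 and Acot4 are neighbouring acyl-CoA thioesterase paralogs whose probe sets can share signal. With the Xist level as a covariate, a setting added after seeing the data, Cyp2b9 (adjusted p = 0.0503), Acot4 (0.0513), Gramd1c (0.0581), Ubd (0.0581) and Tox (0.0685) no longer passed, but most of each change remained. The log2 change of Cyp2b9 was -5.69 with the covariate (SE 1.06, against 0.94 without it) and that of Tox -1.46 (SE 0.32 against 0.29), so these calls ended mainly through a larger error. Acot4 was at -1.58 (SE 0.29 with and without it), Gramd1c at -1.88 (0.37 with and without it) and Ubd at 2.90 (0.58 against 0.63), somewhat smaller changes than without the covariate. Among falls that still passed, Rcan2 was at -1.48, Acot3 at -2.03, Got1 at -1.99 and Chic1 at -2.37. All 12 of the largest falls had their lowest control value on control array 4, the only control with low Xist, as in Rcan2 (8.09 against 9.44 to 9.75).

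At an unadjusted p below 0.05, 2095 genes were higher and 1964 lower. All HCC arrays lay above all control arrays for 1122 genes and below them for 769, which together make 9.48% of the genes against 1.59% expected by chance. The count of calls depended strongly on single arrays. Without HCC array 5 it was 631 higher and 556 lower, among them all 171 and all 32. Without HCC array 1, 2, 3 or 4 it was 115, 66, 49 and 34 higher and 9, 10, 3 and 1 lower. Without control array 1, 2, 3 or 4 it was 15, 13, 10 and 31 higher and 0, 0, 0 and 12 lower in limma, with 3171, 3346, 3122 and 3212 genes of either direction at an unadjusted p below 0.05. Akr1c18, Bicc1, Tmem45a, Scd2 and Meg3 passed under every alternative run on them, and the other 27 of 32 named genes past the threshold lost the call under at least 1.

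Among 12 transcriptional targets of Notch, Sox9, Nrarp and Hes1 rose in HCC. Sox9, a transcription factor of biliary and progenitor cells, went from 7.35 ± 0.14 to 9.50 ± 0.65 (4.43-fold, adjusted p = 0.0228). Nrarp, a feedback regulator of Notch, went from 5.68 ± 0.18 to 7.26 ± 0.40 (2.98-fold, adjusted p = 0.0177), and Hes1, the canonical repressor downstream of Notch, went from 6.93 ± 0.20 to 8.46 ± 0.48 (2.90-fold, adjusted p = 0.0343). None of the 12 fell and 9 did not pass. Adjusted over the list alone 6 were higher, the additional ones being Ccnd1 (9.24 ± 0.47 and 10.76 ± 0.72), Hey2 (4.66 ± 0.09 and 6.14 ± 0.88) and Hey1 (6.55 ± 0.16 and 7.14 ± 0.36). Hey2 was 4.76 on HCC array 2, within the control range. The list median was 0.55 (camera adjusted p = 3.53e-04; adjusted p = 0.338 with an estimated correlation; fry adjusted p = 0.0101), and the list score was 0.77 ± 0.22 in HCC, above every control array on 5 of 5 HCC arrays (exact permutation p = 0.00794, the smallest the design allows; adjusted over 32 lists, 0.0762). Of the 15 lists that passed camera with the preset correlation, Notch targets alone passed fry, and the other 14 had fry adjusted p between 0.052 and 0.477. No list passed camera with an estimated correlation or the adjusted permutation of its score. The adjusted permutation left little room to pass, since a list at the smallest p of 0.00794 could not pass alone after adjustment over 32 lists. The estimated correlation was 0.035 for Notch targets, 0.609 for cell cycle and 0.711 for P450 genes, against the preset 0.01. A preset below the true correlation makes the p-values of camera too small. As given below, 19 of 100 splits of the arrays, the real one included, passed as many lists.

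Notch1 itself, the source of the transgene, measured 7.11 ± 0.13 in control liver and 7.40 ± 0.16 in HCC (log2 change 0.29, 95% interval 0.068 to 0.52, adjusted p = 0.160). Its probe set may include probes outside the NICD part, so it is a weak check of the transgene. Of 21 Notch ligands, receptors and processing enzymes, none passed over all genes. Adjusted over the list alone the nuclear partner Rbpj (8.33 ± 0.14 and 8.83 ± 0.25) was higher and the glycosyltransferase Rfng (7.07 ± 0.14 and 6.64 ± 0.15) lower, and the list median was -0.070 (camera adjusted p = 0.984).

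**Figure D1:**
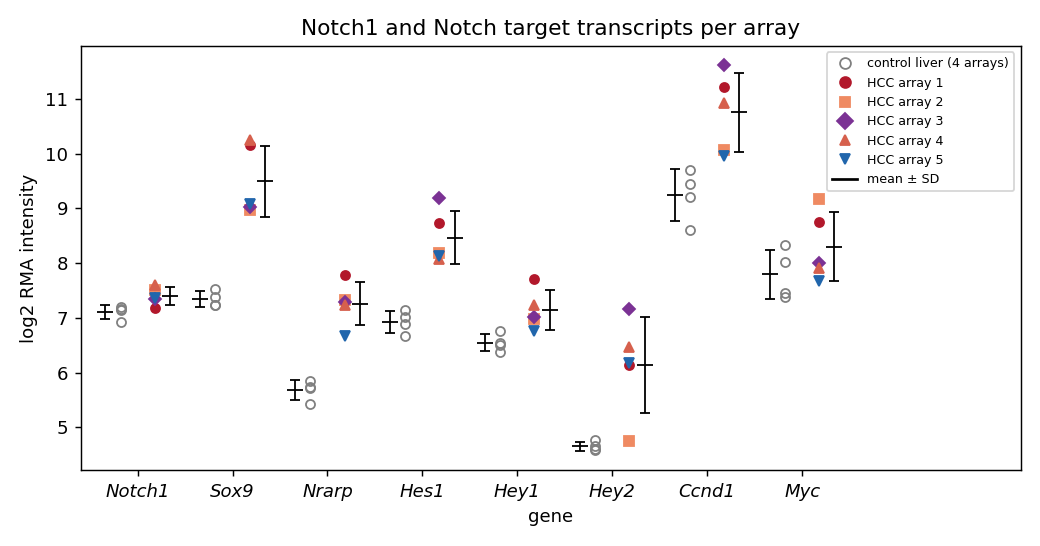
Log2 RMA intensity (vertical axis) of Notch1 and 7 Notch targets (horizontal axis) on each array; open circles are the 4 control livers, filled symbols the 5 HCC arrays, and bars the mean ± SD of each group. Sox9, Nrarp and Hes1 lie above the control range on all 5 HCC arrays, while Hey2 on HCC array 2 (4.76) lies within it.

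Biliary and progenitor markers were higher in HCC as a list by camera with the preset correlation. Of 15 measured members, Bicc1, Cd24a (8.02 ± 0.43 to 10.95 ± 0.99, 7.60-fold, adjusted p = 0.0347) and Sox9 rose, none fell, and 7 were higher adjusted over the list alone. Among those 7, the epithelial adhesion molecule Epcam measured 5.93 ± 0.20 and 7.12 ± 0.53, the tight-junction protein Cldn7 6.75 ± 0.16 and 7.82 ± 0.76, and the cilium-associated cyst protein Pkhd1 6.80 ± 0.42 and 7.70 ± 0.63 in control liver and HCC. The keratins of the bile duct did not pass, with Krt19 at 6.04 ± 0.18 and 6.79 ± 0.80 and Krt7 at 7.12 ± 0.22 and 7.44 ± 0.39. The list median was 0.90 (camera adjusted p = 3.08e-06; adjusted p = 0.343 with an estimated correlation).

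Genes of fetal liver and of HCC were higher as a list by the same test. Of 14 measured members, Tspan8 and Scd2 rose, none fell, and adjusted over the list alone Igf2 was higher as well, with a median of 0.88 (camera adjusted p = 1.82e-05; adjusted p = 0.343 with an estimated correlation). Afp and Dlk1 were among the members that did not pass. Without HCC array 5 the log2 change in limma was 0.23 for Afp (adjusted p = 0.778) and 0.086 for Dlk1 (adjusted p = 0.907). With the Xist level as a covariate it was 0.50 (adjusted p = 0.354) and 0.089 (adjusted p = 0.902). Igf2, the fetal growth factor, measured 6.28 ± 0.11 in control liver and 10.31 ± 2.46 in HCC (adjusted p = 0.104), with 12.1, 11.6, 12.1 and 9.29 on HCC arrays 1, 2, 4 and 5 and 6.41 on HCC array 3. Among 15 imprinted genes, the noncoding RNA Meg3 rose from 7.20 ± 0.19 to 9.79 ± 0.52 (6.02-fold, adjusted p = 0.00561) and none fell. Adjusted over the list alone 3 were higher: Meg3, Igf2 and Rian, a noncoding RNA of the same imprinted domain as Meg3 (4.83 ± 0.64 and 7.57 ± 1.21). The imprinted list had a median of 0.42 (camera adjusted p = 0.00776; adjusted p = 0.343 with an estimated correlation; median 0.066 and adjusted p = 0.135 without HCC array 1).

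Cell cycle genes had the lowest camera p of the 32 lists with the preset correlation. All 34 measured members had a positive log2 change, of which Top2a, the replication-associated topoisomerase (5.91 ± 0.10 to 8.70 ± 1.07, 6.89-fold, adjusted p = 0.0409), and Mcm6, a subunit of the replicative helicase (6.66 ± 0.56 to 9.32 ± 0.44, 6.33-fold, adjusted p = 0.0102), rose. Adjusted over the list alone 27 were higher, among them the mitotic kinase Cdk1 (6.83 ± 0.25 and 8.59 ± 0.82) and the kinetochore motor Cenpe (5.46 ± 0.18 and 7.30 ± 0.83). The list median was 1.01 (camera adjusted p = 2.91e-19; adjusted p = 0.343 with an estimated correlation). Without HCC array 5, the omission with the most calls, the number past the threshold over all genes was 16. A second probe set of Top2a gave 0.097 (adjusted p = 0.826).

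In 6 metabolic lists of the hepatocyte most members had a negative change. Each list was lower by camera with the preset correlation but not by fry (adjusted p 0.0607 to 0.14). By the permutation of the scores the unadjusted p was 0.0238 to 0.0397 and the adjusted p 0.0762 to 0.0977. As given above, that adjustment left little room to pass. Of 22 measured xenobiotic cytochromes P450, 21 had a negative change and Cyp2b9 fell. Adjusted over the list alone 6 were lower, among them Cyp2b13 (10.81 ± 2.90 and 5.24 ± 1.19), Cyp4a14 (12.75 ± 0.61 and 8.29 ± 2.78) and Cyp2c54 (11.92 ± 0.02 and 8.66 ± 2.26), all members of families of similar copies. The list median was -2.24 (camera adjusted p = 4.18e-07; adjusted p = 0.415 with an estimated correlation), and 5 members passed over all genes without HCC array 5. For this and the next metabolic lists, that omission is the one with the most calls in limma. Without control array 1, 2 or 3 no gene was lower past the threshold over all genes. Cyp2b9 and Cyp2b13 differ between the sexes, and Xist and Y-linked levels differed among these arrays as given below.

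Genes of the urea cycle and amino acid breakdown had a negative change in 16 of 16 members. None passed over all genes, and 10 were lower adjusted over the list alone, among them Hgd of tyrosine breakdown (12.60 ± 0.12 and 11.86 ± 0.30, adjusted p = 0.0558 over all genes), Cps1, the entry enzyme of the urea cycle (13.27 ± 0.10 and 12.44 ± 0.50), and the histidine ammonia-lyase Hal (11.18 ± 0.17 and 8.68 ± 1.49). The median was -0.79 (camera adjusted p = 1.31e-06; adjusted p = 0.343 with an estimated correlation). Without HCC array 5, 8 members passed over all genes.

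Fatty acid oxidation had a negative change in 16 of 16 members, with none past the threshold and 8 lower adjusted over the list alone, such as Acadm, the medium-chain acyl-CoA dehydrogenase (12.22 ± 0.19 and 11.41 ± 0.38), and the regulator Ppara (10.30 ± 0.28 and 9.13 ± 0.76); its median was -0.56 (camera adjusted p = 1.74e-05; adjusted p = 0.411 with an estimated correlation). Cholesterol synthesis had a negative change in 14 of 14 members, with none past the threshold and 10 lower adjusted over the list alone, such as Insig1 (10.64 ± 0.22 and 9.85 ± 0.27) and Idi1 (10.28 ± 0.38 and 9.26 ± 0.50). Its median was -0.60 (camera adjusted p = 1.31e-05; adjusted p = 0.343 with an estimated correlation). Fatty acid synthesis had 13 of 14 members negative, none past the threshold and 7 lower adjusted over the list alone, such as Elovl6 (10.69 ± 0.30 and 8.79 ± 1.02) and Thrsp (12.58 ± 0.26 and 10.36 ± 1.22), with a median of -0.55 (camera adjusted p = 2.11e-04; adjusted p = 0.411 with an estimated correlation). Scd1, the main hepatic desaturase, was the positive member (12.60 ± 0.75 and 12.96 ± 0.29, adjusted p = 0.541), in contrast to the rise of Scd2. Without HCC array 5, 6, 4 and 5 members of these lists passed over all genes, in the order given.

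Of 17 bile acid genes 16 had a negative change and none passed, over all genes or adjusted over the list alone. The median was -1.11 (camera adjusted p = 3.36e-05; adjusted p = 0.420 with an estimated correlation). The transporter Slco1a1 measured 10.99 ± 0.27 in control liver and 6.58 ± 2.68 in HCC (adjusted p = 0.104), with 4.99 to 5.79 on HCC arrays 1 to 4 and 11.33 on HCC array 5. Without HCC array 5, 6 bile acid genes passed over all genes.

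Of 22 secreted hepatocyte proteins and liver transcription factors, Prox1, a hepatoblast transcription factor, rose from 9.39 ± 0.25 to 10.20 ± 0.24 (1.75-fold, log2 change 0.81, SE 0.15, adjusted p = 0.0493; with the Xist level as a covariate also 0.81, with a larger SE of 0.17 and an adjusted p of 0.0650), none fell, and adjusted over the list alone 1 was higher and none lower. Alb measured 13.55 ± 0.08 and 13.30 ± 0.23, and the nuclear receptor Nr1i3 11.04 ± 0.48 and 8.15 ± 1.95. The median was -0.20 (camera adjusted p = 0.0262; adjusted p = 0.610 with an estimated correlation; 0.108 after repeated quantile normalisation).

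**Figure D2:**
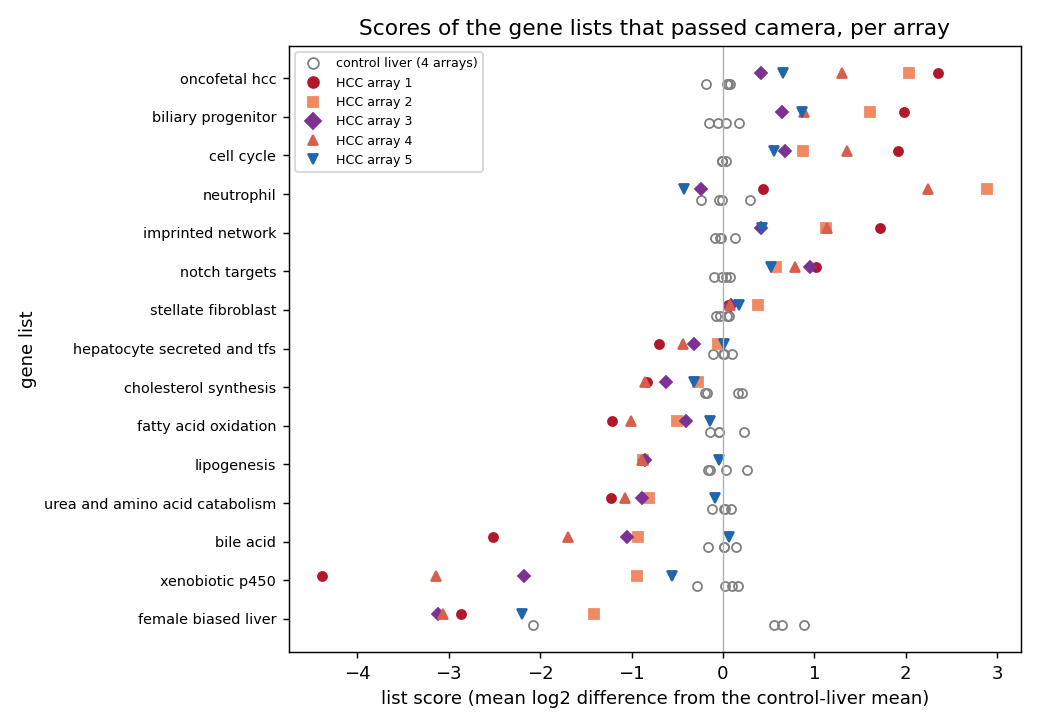
Score of each gene list that passed camera with the preset correlation (vertical axis) on each array, as the mean log2 difference from the control-liver mean (horizontal axis); open circles are the 4 control livers and filled symbols the 5 HCC arrays. HCC array 5 lies nearest to the controls for most metabolic lists, with a bile acid score of 0.071 against -2.52 to -0.93 on the other HCC arrays.

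Female-biased liver genes were lower in HCC by camera with the preset correlation, and the list was also low on control array 4, the control with low Xist. Of 11 members, Cyp2b9 and Acot3 (9.09 ± 0.92 to 6.75 ± 0.45, 5.04-fold, adjusted p = 0.0430) fell, and adjusted over the list alone 6 were lower and 1, Fmo2 (9.77 ± 0.59 and 11.18 ± 0.39), was higher. The median was -2.12 (camera adjusted p = 0.00123; adjusted p = 0.411 with an estimated correlation). Its score was 0.88, 0.55 and 0.64 on control arrays 1 to 3 and -2.08 on control array 4, against -3.12 to -1.41 on the HCC arrays. With the Xist level as a covariate the median was -1.78 (camera adjusted p = 0.0102) and only Acot3 passed (log2 change -2.03, adjusted p = 0.0394), while Cyp2b9 kept its change at -5.69 with a larger error. None of 12 male-biased genes passed, over all genes or adjusted over the list alone; their median was -0.45 (camera adjusted p = 0.482; -1.09 and adjusted p = 0.00597 without HCC array 5), and Cyp4a12a measured 7.21 ± 3.67 and 9.06 ± 3.30.

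Xist, which is transcribed from an inactive X chromosome, lay between 10.68 and 11.76 on control arrays 1, 2 and 3 and was 11.14 and 11.13 on HCC arrays 1 and 2. It was 4.83 on control array 4 and 4.98, 5.10 and 4.92 on HCC arrays 3, 4 and 5. The Y-linked transcript Eif2s3y was 9.10 on control array 4, 8.96 on HCC arrays 3 and 5, 6.05 on HCC array 4 and between 3.42 and 3.86 on the arrays with high Xist. Uty was 7.84 on control array 4, 8.26 and 7.84 on HCC arrays 3 and 5, and 5.29 on HCC array 4. Kdm5d was 8.65 and 8.40 on control array 4 and HCC array 5, and 6.21 and 6.05 on HCC arrays 3 and 4. The list of these 4 transcripts joins Xist with Y-linked genes, which move in opposite directions with sex, so its median (0.23) does not test whether the groups differ in sex.

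**Figure D3:**
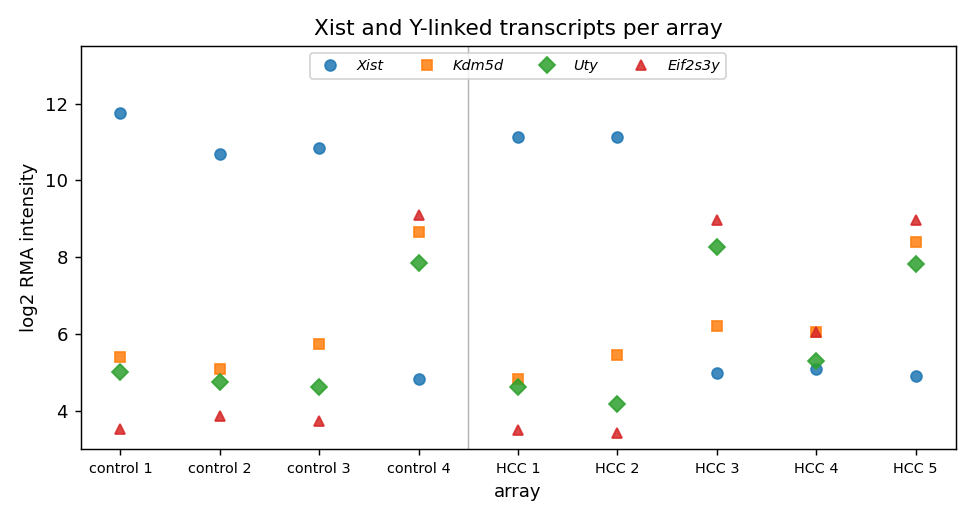
Log2 RMA intensity (vertical axis) of Xist and 3 Y-linked transcripts on each of the 9 arrays (horizontal axis), 1 point per transcript and array. Xist is high on 5 arrays, and on HCC array 4 both Xist (5.10) and Eif2s3y (6.05) are far below their levels on the arrays that express them.

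Of 11 neutrophil genes none passed, over all genes or adjusted over the list alone, with a median of 1.12 (camera adjusted p = 0.0262; adjusted p = 0.643 with an estimated correlation). The neutrophil score was 2.89 and 2.25 on HCC arrays 2 and 4, 0.44 on HCC array 1, and -0.24 and -0.42 on HCC arrays 3 and 5, and without HCC array 2 or 4 the adjusted p was 0.164 and 0.170. Of 19 stellate cell and fibroblast genes none passed, over all genes or adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.0262; adjusted p = 0.343 with an estimated correlation; 0.0946 after repeated quantile normalisation), and Acta2 measured 6.05 ± 0.40 and 7.14 ± 0.69. Of 17 endothelial genes Cd34 rose from 6.35 ± 0.05 to 7.33 ± 0.41 (1.97-fold, adjusted p = 0.0498; 0.0507 after subtraction of array medians), and none fell. The sinusoidal marker Clec4g measured 9.82 ± 0.18 and 8.25 ± 1.47, and the endothelial median was -0.15 (camera adjusted p = 0.319).

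No member passed in the other cell type lists, over all genes or adjusted over the list alone. The medians were -0.033 for 18 macrophage genes (camera adjusted p = 0.907), -0.14 for 15 T and NK cell genes (0.0731), -0.0092 for 10 B and plasma cell genes (0.986), -0.12 for 4 erythroid genes (0.296), -0.10 for 6 pancreatic acinar genes (0.269) and -0.18 for 6 adipocyte genes (0.107). Ccr2, a receptor of recruited monocytes, measured 6.27 ± 0.39 and 7.45 ± 0.70 (adjusted p = 0.123), and its ligand Ccl2 6.73 ± 0.11 and 7.92 ± 0.51 (adjusted p = 0.0530).

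The remaining lists did not shift by camera, and no member passed over all genes. Targets of YAP had a median of 0.17 (adjusted p = 0.0657; 0.0167 with array weights), and 1 of 12, Ajuba, was higher adjusted over the list alone (6.00 ± 0.19 and 6.75 ± 0.29). Glycolysis had a median of -0.0073 (adjusted p = 0.907), with Pfkl, Aldoa and Hk1 higher and Pdk1 and Ldha lower adjusted over the list alone, as in Pdk1 at 9.17 ± 0.18 and 7.88 ± 0.68. The 19 acute phase and cytokine genes had a median of -0.22 (adjusted p = 0.907), with Ccl2 and Hp higher and Hamp, the iron hormone hepcidin (12.87 ± 0.27 and 10.60 ± 1.46), lower adjusted over the list alone. Targets of p53 had a median of 0.079 (adjusted p = 0.296), targets of NRF2 -0.066 (0.986), interferon-stimulated genes -0.047 (0.984), and pericentral and Wnt target genes 0.13 (0.984), with no member of these past the threshold adjusted over the list alone. For glycolysis, NRF2, macrophage and B cell genes camera's direction was up although the median was negative, and for Notch components and pericentral genes the mean and the median differed in sign.

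The tumours differed more among themselves than the control livers did. The root mean square distance of an array to its group mean over all genes was 0.219 ± 0.040 on the log2 scale in control liver and 0.365 ± 0.047 in HCC, a ratio of 1.67 (exact permutation p = 0.00794, two-sided, the smallest the design allows). The first principal component held 48.6% of the variance and placed the control arrays between -35.6 and -30.0 and HCC arrays 1 to 5 at 64.3, 17.0, 18.1, 39.4 and -11.2. HCC array 5 had a median correlation across genes of 0.982 with the control arrays and 0.966 with the other HCC arrays.

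**Figure D4:**
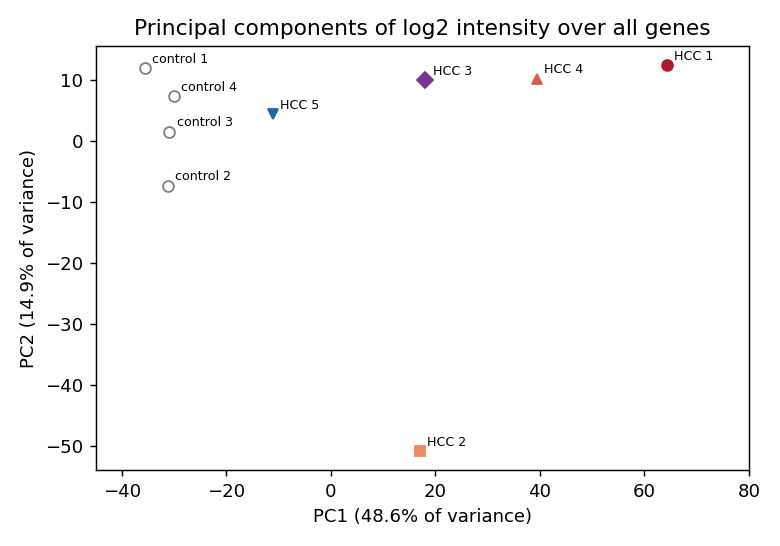
Position of each array on the first (horizontal axis) and second (vertical axis) principal component of log2 intensity over all genes, in component units; open circles are control livers and filled symbols HCC arrays. The 4 control arrays lie between -35.6 and -30.0 on the first component, and HCC array 5 (-11.2) lies between them and the other HCC arrays.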

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

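The tests of the sex-linked transcripts on HCC array 4 and the difference of shares over dimmer genes were chosen only after the result was seen, the Xist level as a covariate, on which the test of the sex makeup rests, was chosen after the sex-linked values were seen but before the list median with it was computed, and the other tests of HCC array 5 and those of other splits of the arrays were set before their results.

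HCC array 5 lay between the control livers and the other tumours. Its lipogenesis score (-0.0431) stood apart from the other HCC arrays (-0.889 to -0.847), as did its Slco1a1 level (11.33 against 4.99 to 5.79) and its erythroid score (0.535 against -0.426 to -0.170). Over 61 genes that were higher in the other tumours HCC array 5 showed a median of 32.0% of their change on the linear scale (95% interval 21.9 to 42.0). This leans against a control liver under a tumour label. The interval resamples the genes of this array, as do those below, so it measures the spread between genes. No control array was put through the same calculation, so the share that a control liver could show is not known. Control-liver RNA mixed into the tumour sample remains open, since the median share over 48 genes that were lower was 33.3% and the difference of the medians was -1.27 percentage points (95% interval -22.2 to 12.01). Over genes with a mean log2 level under 10 in both groups the medians lay further apart, at 26.8% for 49 higher and 63.7% for 15 lower genes (difference -36.9 percentage points, 95% interval -68.4 to 21.1), so equal medians are not established and this interval does not exclude them. Shares of single genes ran widely, with quartiles of 17.8% and 50.6% for the higher and 6.46% and 68.4% for the lower genes, and from -78.0% for Ces3b to 137% for ccdc198 over both sets. The baseline was the mean of 4 controls, 3 of them Xist-high, whereas HCC array 5 had low Xist (4.92). Sex-biased genes may therefore shift the shares of the lower set. Cyp2b13 was at 99.75%, Acot3 at 91.0%, Cyp2b9 at 85.8% and Cyp4a14 at 44.9%, and the male-biased Slco1a1 at -25.1%. The low Xist argues against an Xist-high liver as the source of mixed RNA. A tumour that kept more hepatocyte expression could give these medians too, and no test here separates these.

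The sample structure showed in splits of the 9 arrays as well, of which 100 were taken, the real groups being 1 of them, and every count of splits below includes the real groups. In each split, higher and lower refer to the group of 5 arrays against the group of 4. The real groups gave 171 genes higher. Of the 100 splits 2 gave as many, the real one and another with 749, the highest other value. For genes lower the real count was 32, reached by 2 splits (highest other 646), and for changes of at least 2-fold it was 108 higher, reached by 2 splits (274), and 19 lower, reached by 2 splits (236). The Notch target median of 0.55, compared in absolute value, was reached by 4 splits (highest other 0.70). For these counts and this median the share among the 100 splits taken was below 0.05. The number of lists past camera, 15, was instead reached by 19 splits, with 20 as the highest other. Not every possible split was taken, so the share over all of them is not known. For the Notch target median, reached by 4 splits, it could lie above 0.05. Chance is therefore not excluded for these counts and this median. The split with several times the real count of genes had HCC array 5 and the 4 control livers as its group of 5. Its 749 genes were therefore lower, and its 646 genes higher, in HCC arrays 1 to 4, opposite to the real counts beside them. This split points to a structure of the samples in which HCC array 5 groups with the controls.

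On HCC array 4 both Xist and the Y-linked transcripts were low. Xist was at 1.5% of its mean on the Xist-high arrays (nothing subtracted), which argues against a mixture of RNA from Xist-high and Y-positive animals. The Y-linked transcripts were at 17.9% (Kdm5d), 17.1% (Uty) and 12.6% (Eif2s3y) of their mean on control array 4 and HCC array 5. With their mean on the Xist-high arrays subtracted from both levels as background, these shares were 7.81%, 6.75% and 10.5%. Kdm5d and Uty lay only 0.301 and 0.266 log2 units above the highest Xist-high array, with SDs of 0.352 and 0.306 among the Xist-high arrays, so their shares are close to background, while Eif2s3y lay 2.18 above. Loss of the Y chromosome in most cells of a male tumour stays open, since shares that are all this low must lie near each other (range 3.75 percentage points), which does not test it. A tumour of a female that lost Xist, with RNA of a male mixed in, may give the same values (lowest share after subtraction 6.75%). The 2 cannot be told apart by the Xist and Y-linked values, since none of these differs between them. On HCC array 4 the male-biased score was -1.15 and the female-biased score -3.07, which were not weighed for this. On HCC array 3, which that mean leaves out, Kdm5d was at 20% of it, while Uty was at 134% and Eif2s3y at 95.1% (10.2%, 138% and 94.9% after subtraction), which was not weighed further.

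The female-biased list raised the question of the groups' sex makeup, since 3 of 4 control arrays and 2 of 5 HCC arrays had high Xist. Control array 4 stood apart from the other control arrays in Xist (4.83 against 10.68 to 11.76), in the male-biased score (1.99 against -0.702 to -0.604) and in the female-biased score (-2.08 against 0.554 to 0.882). A different sex makeup as the whole cause is argued against, because with the Xist level as a covariate the list median remained at -1.78, and among the Xist-high arrays alone it was -2.39 with 9 of 11 members lower in HCC. The covariate treats HCC array 4 as Xist-low, although a female that lost Xist was left open for it above. The median among the Xist-high arrays rests on 3 control and 2 HCC arrays and was not tested. Among the Xist-low arrays, which include only 1 control, the median was -0.59 with 7 of 11 lower. A loss of sex-specific liver expression in the tumours is a hypothesis that stays open, and part of the difference may still come from the makeup.

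In all, 18 of 172 groups of arrays held 1 array apart from the rest. Chance alone flags about 1 in 20 of independent groups, but these share arrays and list members. Many of the genes were also named for their separation in these data, so the 18 cannot be set against that rate. On HCC array 2 the interferon score was 1.02 (others -0.560 to -0.226), the macrophage score 1.16 (others -0.496 to -0.207) and Ajuba 7.27 (others 6.58 to 6.67). On HCC array 3 the ammonium transporter Rhbg was 9.86 (others 7.52 to 8.14). Among control arrays, the acute phase score was 0.607 on array 2 (others -0.245 to -0.127), the oncofetal score -0.182 on array 4 (others 0.0461 to 0.0752) and the YAP target score -0.124 on array 3 (others 0.0271 to 0.0559). Top2a was 5.76 on control array 4 (others 5.96 to 5.97), Pfkl 6.30 and Mmp8 4.54 on control array 1 (others 6.88 to 6.91 and 4.67 to 4.68), and Prf1 6.86 and Cd34 6.43 on control array 2 (others 6.983 to 6.995 and 6.32 to 6.34). Of 13723 probe sets without a single gene symbol, which no comparison above used, 2 were higher and 0 lower in HCC by limma, with 1213 at an unadjusted p below 0.05.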

How the results depend on the processing

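The Xist covariate was chosen after seeing the data, and the other alternatives were planned. The direction of Notch1 (0.23 to 0.35), of the Notch target median (0.42 to 0.72) and of the larger spread in HCC (ratio 1.51 to 2.92) was kept under every alternative run on them, as was the side of the threshold, except that the Notch target list (median 0.55) no longer passed camera with an estimated correlation (adjusted p = 0.338), as no list did; the cause was not tested. The gene counts were less stable than the directions. Against 171 genes higher, 32 lower, 108 at least 2-fold higher and 19 at least 2-fold lower, genes with a mean above the median gave 285 higher, 93 lower and 50 at least 2-fold lower, where fewer genes are adjusted for. Repeated quantile normalisation gave 49 lower, and 127 of its 151 higher genes were shared with the unaltered values. Array weights gave 503 and 246, with 194 and 93 at least 2-fold, and the Y-linked mean as a covariate 321 and 124, with 188 and 55 at least 2-fold. For the filter, the normalisation, the weights and this covariate the cause of the changed counts was not tested. The Xist covariate gave 201 higher and 32 lower, of which 131 and 18 were shared with the fit without it.

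Leaving out 1 array at a time gave 10 to 631 genes higher, 0 to 556 lower, 9 to 278 at least 2-fold higher and 0 to 238 at least 2-fold lower. The highest values all came without HCC array 5, and the lowest without control array 3 (for the lower genes, without control array 1, 2 or 3). The replicate block, which also leaves out HCC array 5, gave 259 higher, 220 lower and 143 at least 2-fold lower, below the 631 and 556 of the same arrays without the block. No pairing by replicate number was stated in the labels. The correlation of the deviations of same-numbered arrays was -0.004, 0.32, -0.029 and -0.083, and only control array 2 correlated best with its own number among the HCC arrays. These few values give no clear sign of a pairing and cannot exclude one. Wfdc3 turned to -0.048 on its second probe set when every probe set was tested on its own. The cause was not tested.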

Other observations

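The tests below were chosen after the expression of these tumours was seen, except that the list of ciliary genes was written before its own result was computed.

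The 5 tumours were unlike one another in features that the group comparison averages. HCC array 3 had a pericentral and Wnt target score of 1.14, against -0.65 to -0.076 on the other HCC arrays and -0.14 to 0.19 on the control arrays. On that array the Wnt receptor partner Lgr5 was 10.1, the feedback regulator Axin2 8.92, the glutamate transporter Slc1a2 12.1 and Glul, the glutamine synthetase of pericentral hepatocytes, 12.8, while Igf2 was 6.41, near the control level of 6.28 ± 0.11. HCC array 2 had the highest macrophage (1.16), interferon (1.02) and neutrophil (2.89) scores, with the monocyte receptor Cd14 at 11.3 against 6.89 ± 0.64 in control liver. HCC array 1 had the highest cell cycle (1.91), biliary (1.98) and oncofetal (2.35) scores and the lowest P450 score (-4.38), with the chloride channel Cftr at 10.8, the oncofetal proteoglycan Gpc3 at 10.5 and the imprinted Peg3 at 11.3. The surface protein Ly6d was 11.9 on both HCC arrays 1 and 2 and between 6.5 and 7.2 on the other HCC arrays.

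Genes of the primary cilium, an antenna-like organelle that bile duct cells carry and hepatocytes lack, were higher in HCC. The question arose from Ift81 and Dync2li1, components of transport within the cilium that rose in HCC (log2 change 1.53 and 2.21, adjusted p = 0.0179 and 0.0150), and it was tested on 52 other measured ciliary genes. Of these, 42 had a positive change and 2 passed over all genes, the transition zone proteins Cep290 (1.00, adjusted p = 0.0346) and Rpgrip1l (0.73, adjusted p = 0.0493), while 25 were higher and 0 lower in limma at an unadjusted p below 0.05. The median was 0.29 (camera p = 1.03e-10; p = 0.0421 with an estimated correlation; fry p = 0.00635), and the score was 0.37 ± 0.17 in HCC against an SD of 0.087 in control liver (exact permutation p = 0.00794, the smallest the design allows). The p-values of the ciliary set are unadjusted, since it was tested alone, whereas those of the 32 lists are adjusted over the lists. They therefore do not rank this set above the lists. Whether tumour cells express more of these genes or the share of ciliated cells changed was not tested.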
